A study of Mus musculus with 37 samples.

How the data were processed

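RNA was measured by sequencing in bulk mouse cortex, with 1 library per sample, and all 37 libraries of the series were used. Per the labels the RNA was polyA selected, extracted with Direct-zol kits and made into libraries with NEB Next Ultra reagents. The groups are C57BL6/J at 3 months (n = 10) and 24 months (n = 8), Ifnar1fl/fl at 3 months (n = 4) and 24 months (n = 6), and Ifnar1fl/fl;Cx3cr1-CreERT2 at 3 months (n = 4) and 24 months (n = 5). Sex, litter, sequencing date and any treatment that would switch on an inducible Cre are not given in the sources used here.

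The deposited values are FPKM, made by the authors, in one table for the 18 C57BL6/J libraries and another for the 19 Ifnar1 libraries. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, their versions and the annotation release are not given in the sources used here. Counts were not used here. The C57BL6/J table holds 34475 genes, and there are 33821 in the Ifnar1 table. Of the latter, 28393 have a value in all 19 libraries, 4013 only in the 24-month libraries and 1415 only in the 3-month libraries, as would be seen in a table joined from values made separately for each age. The 10 genes most abundant in the C57BL6/J table, 18S ribosomal RNA and mitochondrial transcripts, have no line in the Ifnar1 table. Because the tables were normalized separately, p-values were computed only within a table, and values set side by side across the tables only describe. Within the Ifnar1 table the sample titles start with MKO for the 3-month and IC for the 24-month libraries. The age p-values of the Ifnar1 groups therefore compare columns that may also have been made and normalized separately. Gene coordinates, lengths and GC content were taken from GENCODE M21 (GRCm38), which holds 32625 of the C57BL6/J identifiers and 32059 of the Ifnar1 identifiers.

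Relative depth was estimated within each cohort from the most frequent ratio between libraries among genes below 0.2 FPKM, where few reads give repeated ratios. A pseudocount of 0.5 FPKM was added before taking log2, and genes with a mean of at least 0.5 FPKM over the libraries of a fit were tested, 15180 in C57BL6/J and 15516 in the Ifnar1 groups. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a variance trend and robust moderation, and p-values are two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes come from differences between group means of the log2 values. They are thus ratios of geometric means of FPKM plus the pseudocount, and can differ from ratios of the mean FPKM printed beside them. The p-values measure the spread between libraries as labelled, 1 per sample. The comparisons were age in each of the 3 genotypes, Cre carriers minus Ifnar1fl/fl at each age, and the difference of the age change between those genotypes. All 4 Ifnar1 groups shared 1 fit.

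Before the data were examined, 39 gene lists were fixed, 21 of pathways and quality signs and 18 of cell types and neighbouring tissues, of which 37 had at least 3 members past the filter. The lists of T and NK cells and of neutrophils and monocytes had too few. The list called heat shock below holds genes of both the heat shock and the unfolded protein response. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Members were also adjusted over the list alone. Counts of members raised or lowered are out of those past the filter. A list score per library is the mean deviation of log2 values of its members from the mean of each gene over the libraries of the table, and differences of scores were tested by exact permutation of the libraries. Genes named below are Ifnar1 and Cx3cr1 in every comparison, the 12 with the largest positive and the 12 with the largest negative log2 fold change among those with an adjusted p below 0.05 and at least 1 FPKM in the higher group, and members of the fixed lists. Names of clone type or with a pseudogene suffix, immunoglobulin and T cell receptor segments, some small RNA families, and Xist, Tsix and Y-linked genes were left out of those 12. Where no gene passed, the 5 with the lowest p are given. Genes raised or lowered with age in C57BL6/J, at an absolute log2 fold change of at least 0.58, were also tested as sets in the Ifnar1 fit.

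The alternatives set in advance were pseudocounts of 0.1 and 1, a filter at 2 FPKM or none, sums rescaled to 1000000, median-ratio scaling, quantile normalization, moderation without the robust option, array weights, Xist as a covariate, fits of only the groups compared, an exact rank-sum test in C57BL6/J, sets by adjusted p only, and leaving out each library. The others, chosen after seeing the data, were removal of the libraries with low 18S or with at least 20 FPKM of Ttr, rescaling without 18S and mitochondrial genes, covariates of Ttr or Drd2, removal of trends with GC content or with GC content and length, and exact permutation of list scores. The procedure was tested on simulated data made from the group structure, with 100 genes changed by 1.5-fold and 100 by 2-fold. At a 2-fold change limma recovered 91% of the 100 in the C57BL6/J age design, 84% at 3 months and 88% at 24 months in the genotype designs, and 76% for the difference of age changes. At 1.5-fold it recovered 89%, 70%, 73% and 44%. Between 3 and 14 unchanged genes were called in each design. None of 30 unchanged simulated sets was called by camera. The simulated genes varied independently, so this result says nothing about lists whose genes vary together. With 200 genes changed at once, recovery may also be higher than for a single changed gene.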

Results

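The series asks about type I interferon signalling in the aging mouse brain, by its title. Cortex RNA was measured in C57BL6/J mice of 3 months (n = 10) and 24 months (n = 8), and at the same ages in mice with a floxed type I interferon receptor gene, Ifnar1fl/fl (n = 4 and n = 6), and in floxed mice that also carry a Cre recombinase at the locus of the microglial gene Cx3cr1, Ifnar1fl/fl;Cx3cr1-CreERT2 (n = 4 and n = 5). Relative depth ran from 0.790 to 1.45 of the median in the C57BL6/J libraries, from 0.883 to 1.23 in the 24-month and from 0.917 to 1.13 in the 3-month Ifnar1 libraries. Between 13006 and 13210 genes reached 1 FPKM in the C57BL6/J libraries, 13241 to 13460 in the 3-month and 12968 to 13491 in the 24-month Ifnar1 libraries. The 10 most abundant genes took 14.3% to 28.3% of the FPKM sum in C57BL6/J. They took 3.23% to 3.81% and 3.51% to 4.94% in the 3-month and 24-month Ifnar1 libraries, whose table lacks 18S ribosomal RNA and the most abundant mitochondrial transcripts. No pair of libraries was identical, and libraries of a group correlated across genes at 0.963 to 0.986.

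The first comparison asks what age changed in C57BL6/J cortex. The complement gene C4b (ENSMUSG00000073418, mm10 chromosome 17, 34728380 to 34743882) rose from 3.27 ± 0.750 FPKM (SD, n = 10) at 3 months to 17.3 ± 3.77 FPKM (SD, n = 8) at 24 months, 4.72-fold. The lysozyme gene Lyz2 rose 2.48-fold, from 6.58 ± 1.34 to 17.6 ± 6.01 FPKM, and the reactive astrocyte genes Serpina3n and Gfap rose 2.32-fold and 1.97-fold, Gfap from 46.9 ± 6.08 to 95.1 ± 26.2 FPKM. Gpr17, a receptor of newly forming oligodendrocytes, fell by 0.82 in log2 (SE 0.07), from 9.11 ± 0.706 to 4.98 ± 0.731 FPKM. Neither targeted gene passed: Ifnar1 stood at 6.79 ± 0.447 and 6.38 ± 0.503 FPKM (adjusted p = 0.329) and Cx3cr1 at 10.0 ± 0.849 and 11.2 ± 1.03 FPKM (adjusted p = 0.104).

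Interferon and antigen presentation genes rose together. Of the 54 genes in the list of type I interferon-stimulated genes 29 were past the filter. Of these 29 genes 11 rose and none fell, 18 adjusted over the list alone, with a list median of 0.25 in log2. Among them Ifit1 rose by 0.70 (SE 0.14), Ifitm3 by 0.70 (SE 0.12), Bst2 by 0.63 (SE 0.15) and Ifi27 by 0.57 (SE 0.07). The list had an adjusted p of 1.51e-13, and 0.0147 with an estimated correlation. Its library scores averaged 0.17 ± 0.10 (SD, n = 8) at 24 months against -0.14 ± 0.12 (SD, n = 10) at 3 months (exact permutation p = 4.57e-05, adjusted 0.000282). Of 17 genes of MHC class I presentation 8 rose, 13 adjusted over the list alone, including H2-K1 (0.79, SE 0.07), H2-D1 (0.57, SE 0.09) and B2m (0.48, SE 0.06), with an adjusted p of 0.000448 with an estimated correlation. Of 6 MHC class II genes 3 rose, 4 adjusted over the list alone, led by the invariant chain Cd74 (0.77, SE 0.16), at an adjusted p of 0.0185 with an estimated correlation.

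**Figure D1:**
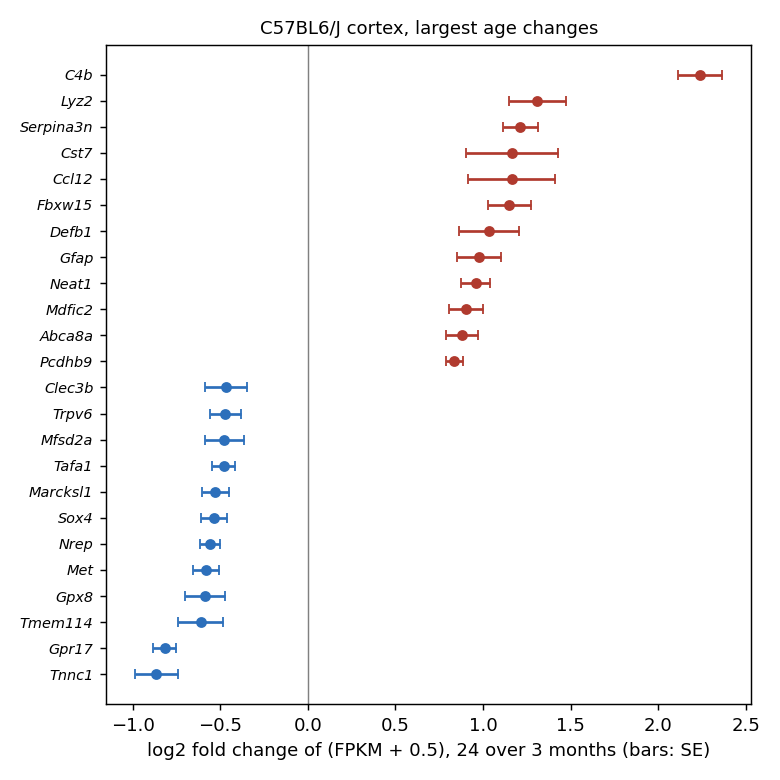
Log2 fold change between 24 months (n = 8) and 3 months (n = 10) of the 12 most raised and 12 most lowered named genes in C57BL6/J cortex, with bars for the standard error. C4b stands at 2.24 and Tnnc1 at -0.86.

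Microglial, complement and reactive astrocyte genes rose as well. Of 22 disease-associated microglia genes 13 rose, 15 adjusted over the list alone, among them Cst7 (1.16, SE 0.26), Cd68 (0.50, SE 0.08) and Tyrobp (0.47, SE 0.08). Of 11 complement genes 6 rose, 7 adjusted over the list alone, C1qa by 0.50, C1qb by 0.46 and C1qc by 0.39. Of 33 lysosome and phagocytosis genes 10 rose, 14 adjusted over the list alone, with Ctss at 0.60 (SE 0.05) and the Fc receptor gene Fcgr3 at 0.41. These 3 lists each had an adjusted p of 0.0147 with an estimated correlation. Of 20 reactive astrocyte genes 7 rose, 8 adjusted over the list alone, including Vim (0.52, SE 0.11), at 0.0368 with an estimated correlation. The chemokine Ccl12 (1.16, SE 0.25) was the 1 of 11 cytokine, chemokine and NF-kB genes that rose, the same 1 adjusted over the list alone, at 0.0475 with an estimated correlation. Of 18 homeostatic microglia genes 5 rose, Trem2 among them (0.37, SE 0.06), and Csf1r fell by 0.13 (SE 0.03), 9 and 1 adjusted over the list alone. That list lost its call with an estimated correlation (adjusted p = 0.0688) and passed by exact permutation of library scores (adjusted p = 0.000538).

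Neuronal and other glial groups changed too. Of 37 synaptic genes 7 fell, Grin2b by 0.27 (SE 0.04) and Dlg4 by 0.19 (SE 0.05), 12 adjusted over the list alone, with 1 raised there, at an adjusted p of 0.0475 with an estimated correlation. Of 27 clustered protocadherins, neuronal adhesion genes, 9 rose and Pcdhgc5 fell by 0.30 (SE 0.05), 12 and 1 adjusted over the list alone (adjusted p = 0.0147 with an estimated correlation). Pcdhb9 rose 1.79-fold, from 4.39 ± 0.372 to 8.24 ± 0.622 FPKM. Of 19 cholesterol synthesis genes 6 rose, 6 adjusted over the list alone, with Insig1 at 0.31 (adjusted p = 0.0300 with an estimated correlation). Of 18 myelin genes 9 rose, 9 adjusted over the list alone, Apod by 0.69 and Trf by 0.56, and of 40 ribosomal protein genes 9 rose, 14 adjusted over the list alone, but both lists lost their call with an estimated correlation (adjusted p = 0.179 for each). By exact permutation of library scores the myelin list passed (adjusted p = 0.00151) and the ribosomal list did not (adjusted p = 0.0875). Among the precursor and new oligodendrocyte genes 4 of 16 fell, Gpr17 and Neu4 (-0.39) included, with 4 lowered and 2 raised adjusted over the list alone (adjusted p = 0.242 with an estimated correlation, and 0.0423 by exact permutation).

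Markers of other tissues also moved in C57BL6/J. Of 12 striatal markers 3 fell, Pde10a by 0.27 among them, 7 adjusted over the list alone, with a list median of -0.14 (adjusted p = 0.000827, and 0.280 with an estimated correlation). The choroid plexus marker Ttr ranged widely between libraries, at 39.3 ± 79.4 FPKM at 3 months and 56.2 ± 114 FPKM at 24 months, and its list did not pass (6 genes, median 0.17, adjusted p = 0.231). The thalamus list (8 genes, median 0.20, adjusted p = 0.0430) lost its call with an estimated correlation (adjusted p = 0.280), as did the excitatory neuron list (-0.09, adjusted p = 0.272), the inhibitory neuron list (0.09, adjusted p = 0.280), the fibroblast list (-0.09, adjusted p = 0.378) and the B and plasma cell list (0.35, adjusted p = 0.130), where Igkc rose by 2.44 (SE 0.36). By exact permutation of library scores the B and plasma cell list (adjusted p = 0.000470) and the excitatory neuron list (adjusted p = 0.0324) passed, and the striatum, thalamus, inhibitory neuron and fibroblast lists did not (adjusted p from 0.0506 to 0.137). In all 21 of 37 lists passed, 16 upward and 5 downward, and 11 held with an estimated correlation. With the preset one, the thalamus, inhibitory neuron, fibroblast, precursor and new oligodendrocyte, excitatory neuron, cytokine and protocadherin lists lost their call in at least 1 other setting. Lists that did not pass were senescence, immediate early, oxidative phosphorylation, mitochondrially encoded, heat shock, circadian clock, glucocorticoid, extracellular matrix, astrocyte, endothelial, pericyte, choroid plexus, ependymal, border-associated macrophage, erythroid and hippocampus, with medians between -0.09 and 0.51.

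By limma 1051 of 15180 genes passed in C57BL6/J, 564 higher and 487 lower, of which 64 and 6 changed by at least 1.5-fold, and 3112 had an unadjusted p below 0.05. The other named genes that rose were Fbxw15 (1.15), Defb1 (1.04), the nuclear RNA Neat1 (0.96), Mdfic2 (0.90) and Abca8a (0.88), and those that fell were Tnnc1 (-0.86), Tmem114 (-0.61), Gpx8 (-0.59), Met (-0.58), Nrep (-0.56), Sox4 (-0.54), Marcksl1 (-0.53), Tafa1 (-0.48), the lipid transporter Mfsd2a (-0.48), Trpv6 (-0.47) and Clec3b (-0.47). Of these 24 genes 19 passed under every alternative, and Cst7, Tmem114, Gpx8, Mfsd2a and Clec3b did not. The count was 518, with 88.2% higher against 53.7%, after rescaling to sums of 1000000. That rescaling raises all values and so also loosens the filter (20017 genes tested) and shrinks the relative pseudocount. A pseudocount of 0.1 alone gave 1046 genes (53.3% higher) and no filter alone gave 717 (61.4% higher), so neither alone gave that share. Rescaling without 18S and mitochondrial genes gave 1031 (52.9% higher). The count was 594 without the libraries low in 18S (5, 8 and 17), and 329 without the 5 libraries with at least 20 FPKM of Ttr.

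The age comparison was then made in the Ifnar1 groups, where the columns of each age also list partly different genes, so a difference of cohort, dissection or processing cannot be told apart from age. In Ifnar1fl/fl the complement gene C4b rose by 2.18 (SE 0.31) and Serpina3n rose 5.12-fold, from 4.04 ± 0.476 FPKM (SD, n = 4) to 26.3 ± 16.9 FPKM (SD, n = 6). The striatal dopamine receptor gene Drd2 rose 9.52-fold (3.25, SE 0.46) from 2.45 ± 3.06 FPKM. Its 3-month mean is raised by library 58 at 7.03 FPKM, with the others at 0.769 to 1.18 FPKM. The metal-binding gene Mt2 fell from 14.1 ± 5.44 to 0.398 ± 0.433 FPKM. In the Cre carriers C4b rose 4.21-fold, Drd2 8.46-fold, from 2.29 ± 1.96 FPKM (SD, n = 4) to 18.6 ± 3.83 FPKM (SD, n = 5), and Mt2 fell from 12.7 ± 2.37 to 0.221 ± 0.220 FPKM. In C57BL6/J Drd2 stood at 19.9 ± 1.52 FPKM at 3 months and 18.1 ± 1.47 FPKM at 24 months, both near the 24-month Ifnar1 values. Ifnar1 fell by 0.24 (SE 0.07, adjusted p = 0.00958) in Ifnar1fl/fl and stood at -0.17 (adjusted p = 0.0681) in Cre carriers, and Cx3cr1 rose by 0.45 (SE 0.15, adjusted p = 0.0261) and 0.56 (SE 0.16, adjusted p = 0.00914).

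Immune and glial groups rose again with age. Of 33 interferon-stimulated genes 19 rose in Ifnar1fl/fl, 22 adjusted over the list alone, and in Cre carriers 9 rose and 2 fell, the same counts adjusted over the list alone. Ifit1 rose by 0.93 and 1.01, and Irf9 fell by 0.46 in Cre carriers. The list medians were 0.56 and 0.34, and both lost their call with an estimated correlation (adjusted p = 0.247 and 0.451). Of 24 disease-associated microglia genes 14 and 9 rose, 16 and 10 adjusted over the list alone, Lyz2 by 2.09 and 1.74 and Clec7a by 1.90 and 1.23 (adjusted p = 0.249 and 0.451 with an estimated correlation). Of 12 complement genes 7 and 5 rose, as many adjusted over the list alone (adjusted p = 0.247 and 0.434 with an estimated correlation), and of 20 reactive astrocyte genes 11 and 6, as many adjusted over the list alone (adjusted p = 0.247 and 0.436). Of 18 myelin genes 15 and 16 rose, as many adjusted over the list alone, Mobp by 1.27 in Ifnar1fl/fl (adjusted p = 0.230 and 0.416 with an estimated correlation). No list of either genotype held with an estimated correlation, against 20 and 21 that passed with the preset one.

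Striatal, choroid plexus, immediate early, and heat shock and unfolded protein response genes moved with them. Whether their age change differs from that in C57BL6/J was not tested. All 12 striatal markers rose in each genotype, 12 adjusted over the list alone, with list medians of 1.89 and 1.73, and Drd2, Penk and Adora2a among the largest (adjusted p = 0.230 and 0.416 with an estimated correlation). The choroid plexus gene Ttr rose from 0.692 ± 0.408 to 40.3 ± 57.1 FPKM in Ifnar1fl/fl and by 3.27 (SE 1.21) to 19.6 ± 21.6 FPKM in Cre carriers, with 2 and 3 of the 6 list members raised, as many adjusted over the list alone (adjusted p = 0.247 and 0.434 with an estimated correlation). Immediate early genes, which report recent neuronal activity, fell in 14 and 8 of 21 cases, 15 and 11 adjusted over the list alone. Genes of the heat shock and unfolded protein response list fell in 19 and 14 of 24 cases. Adjusted over the list alone 20 and 14 of them fell, with 1 raised in Cre carriers. Their adjusted p with an estimated correlation was 0.605 and 0.643 for the first list and 0.247 and 0.434 for the second. With Drd2 as a covariate the immediate early list turned to medians of 0.06 and 0.03 and no longer passed. In Ifnar1fl/fl 7 other lists lost their call with it, choroid plexus among them, and in Cre carriers 12 others, with choroid plexus, heat shock and striatum among them.

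Further lists passed in the Ifnar1 groups. In Ifnar1fl/fl those that passed upward were MHC class I (9 raised and 1 lowered of 17, 11 and 1 adjusted over the list alone), MHC class II, homeostatic microglia, lysosome, cytokines, ribosomal proteins, inhibitory neurons, endothelium, ependyma, border-associated macrophages and hippocampus. Their adjusted p with an estimated correlation lay between 0.230 and 0.665. In Cre carriers those upward were MHC class I (2 raised and 1 lowered, 0 and 1 adjusted over the list alone), MHC class II, homeostatic microglia, protocadherins, mitochondrially encoded, cholesterol synthesis, inhibitory neurons, endothelium, ependyma, B and plasma cells, hippocampus and thalamus. Theirs were 0.434 or higher. The mitochondrially encoded list has 6 members here, against 13 in C57BL6/J, since the others are absent from the Ifnar1 table. With the preset correlation, MHC class II, mitochondrially encoded, endothelium, B and plasma cells, hippocampus and thalamus lost their call in Cre carriers under median-ratio scaling, quantile normalization and both rescalings. In Ifnar1fl/fl the hippocampus list lost its call under these 4 scalings, and the cytokine and border-associated macrophage lists under 3 of them and without Ifnar1fl/fl 230, and MHC class II under 2 of them. In Cre carriers cholesterol synthesis lost its call in 1 of 17 settings and without 4 of the 9 libraries in turn, and MHC class I in 3 settings. With Ttr as a covariate 10 of 21 lists lost their call in Cre carriers and 4 of 20 in Ifnar1fl/fl.

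**Figure D2:**
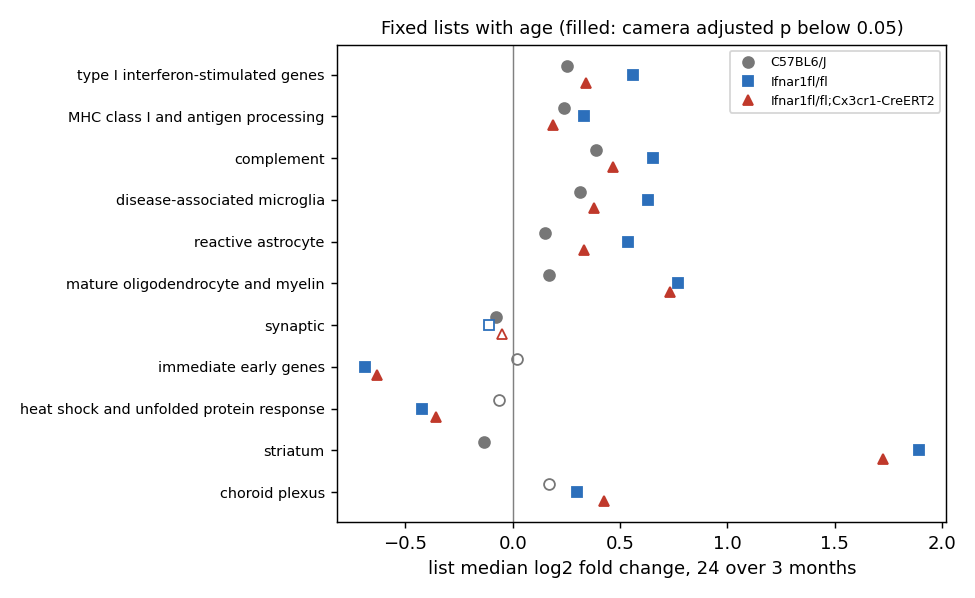
Median log2 fold change between 24 and 3 months of 11 fixed lists in C57BL6/J (grey circles), Ifnar1fl/fl (blue squares) and Ifnar1fl/fl;Cx3cr1-CreERT2 (red triangles), filled where camera with the preset correlation passed. The striatum list stands at -0.14, 1.89 and 1.73.

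Among the most changed named genes were very short transcripts. The mitochondrial tRNA mt-Ts2 rose 10.2-fold and 8.02-fold, and mt-Th and mt-Tr rose in both genotypes, mt-Tt in Ifnar1fl/fl, all of them with annotated lengths of 59 to 68 bases. MicroRNA precursors annotated at 56 to 108 bases made up 8 of the 12 most lowered genes in Ifnar1fl/fl and 9 in Cre carriers, Mir374b and Mir343 among them. All of them except Mir5620 overlap another gene on the same strand, such as Ftx for Mir374b, Ercc2 for Mir343 and Camk2a for Mir6982. These values cannot tell reads of a microRNA precursor from reads of the gene around it. The other lowered genes were Rpl24, MIR628 and Tpi-rs11, annotated as a processed pseudogene, in Ifnar1fl/fl, and Rpl24 and Miat in Cre carriers. MIR628 has the name of a microRNA but no entry in GENCODE M21. Rpl24 went from only 4.24 to 0.634 FPKM in Ifnar1fl/fl and overlaps Gm28037 on the same strand. How reads were assigned between these 2 genes is not known. The other raised genes were Lrrc10b and Scn4b in both, Six3 (2.46, SE 0.31) in Ifnar1fl/fl, and Rn7sk and Lars2 in Cre carriers. Miat, a long noncoding RNA, went from 29.6 ± 2.68 to 5.76 ± 1.20 FPKM in Cre carriers, and stood at 6.41 ± 1.01 FPKM in 3-month C57BL6/J. Mt1, the neighbour of Mt2, rose by 1.01 and 0.86 where Mt2 fell.

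A comparison across the tables was added after these values were seen. With the median shift between tables removed, 3-month C57BL6/J lay closer to the 24-month than to the 3-month libraries for 77.8% of 5595 genes that passed in Ifnar1fl/fl, and for 85.9% of 5528 that passed in Cre carriers. This held for 12 of 12 striatal markers and 12 of 15 myelin genes in Ifnar1fl/fl. It did not hold for 15 of 15 interferon-stimulated, 10 of 12 disease-associated microglia, 5 of 6 complement, 9 of 11 reactive astrocyte and 9 of 10 protocadherin genes there, where 3-month C57BL6/J lay closer to the 3-month libraries. In Cre carriers 3-month C57BL6/J lay closer to the 24-month libraries for 8 of 10 interferon-stimulated genes, 3 of 8 disease-associated microglia genes and 1 of 13 protocadherins.

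By limma 5762 of 15516 genes passed in Ifnar1fl/fl, 1369 higher and 4393 lower, and 5725 in Cre carriers, 1452 higher and 4273 lower. The median over all genes was -0.12 and -0.10, and it moved to -0.01 and -0.000199 with median-ratio scaling, by which the share that was higher went from 23.8% to 48.6% and from 25.4% to 46.1%. It was 46.8% and 46.1% with sums of 1000000 (20956 genes tested), 48.2% and 49.9% with quantile normalization, and 48.8% and 47.0% with GC trends removed, so the direction of small changes rests on the scaling. With Drd2, which nearly separates the ages here, as a covariate 375 and 1187 genes passed. Of the named genes that passed, 6 of 26 in Ifnar1fl/fl and 8 of 25 in Cre carriers did so under every alternative, Drd2 among them in both, although it could not be tested with itself as covariate. Serpina3n, Six3, Ttr, Ifnar1 and Cx3cr1 in Ifnar1fl/fl and C4b, Ttr, Scn4b, Lars2 and Cx3cr1 in Cre carriers did not. Age changes correlated at 0.818 across 15516 genes between both genotypes, and at 0.278 and 0.263 across 14941 genes with those of C57BL6/J, where genes are not independent replicates. Of 561 genes raised in C57BL6/J 249 were also raised in Ifnar1fl/fl, against 50.5 for independent calls. Of 483 lowered genes 236 were lowered in Ifnar1fl/fl, against 137, and 187 in Cre carriers, against 132. Genes that passed in C57BL6/J and passed in the opposite direction numbered 63 in Ifnar1fl/fl and 77 in Cre carriers. The 65 genes raised in C57BL6/J by a log2 of at least 0.58 had medians of 0.77 and 0.80, and held with an estimated correlation (adjusted p = 0.00189 and 0.00262). The 6 measured genes lowered that far did not pass (medians of -0.39 and -0.57, adjusted p = 0.153 and 0.0516), and the 483 lowered by any amount passed but lost their call with an estimated correlation (adjusted p = 0.161 and 0.392).

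The next question was what the Cre allele and the receptor deletion it is designed for changed in the whole cortex. At 3 months Cx3cr1 (ENSMUSG00000052336, mm10 chromosome 9, 119901616 to 120069879), the gene whose locus carries the Cre, stood at 3.87 ± 0.547 FPKM (SD, n = 4) in Cre carriers and 9.12 ± 0.923 FPKM (SD, n = 4) in Ifnar1fl/fl, 2.21-fold lower, by -1.14 in log2 (SE 0.17, adjusted p = 0.0248). At 24 months it stood at 5.92 ± 0.620 FPKM (SD, n = 5) and 13.0 ± 3.95 FPKM (SD, n = 6), 2.05-fold lower, by -1.03 (SE 0.14, adjusted p = 0.0119). No library of the carriers overlapped the Ifnar1fl/fl range at either age, at exact permutation p-values of 0.0286 and 0.00216, the smallest these group sizes allow. The annotated span of Cx3cr1 overlaps Gorasp1, Csrnp1 and Xirp1 on the same strand, and further genes on the other. How reads were assigned between these genes is not known. Ifnar1 (ENSMUSG00000022967, mm10 chromosome 16, 91485238 to 91507441) stood at 8.85 ± 0.612 against 9.07 ± 0.706 FPKM at 3 months and at 7.80 ± 0.413 against 7.59 ± 0.648 FPKM at 24 months, with differences of -0.03 (exact permutation p = 0.657) and 0.04 (exact permutation p = 0.522). A deletion limited to microglia was not detectable in these whole-gene values of bulk cortex.

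**Figure D3:**
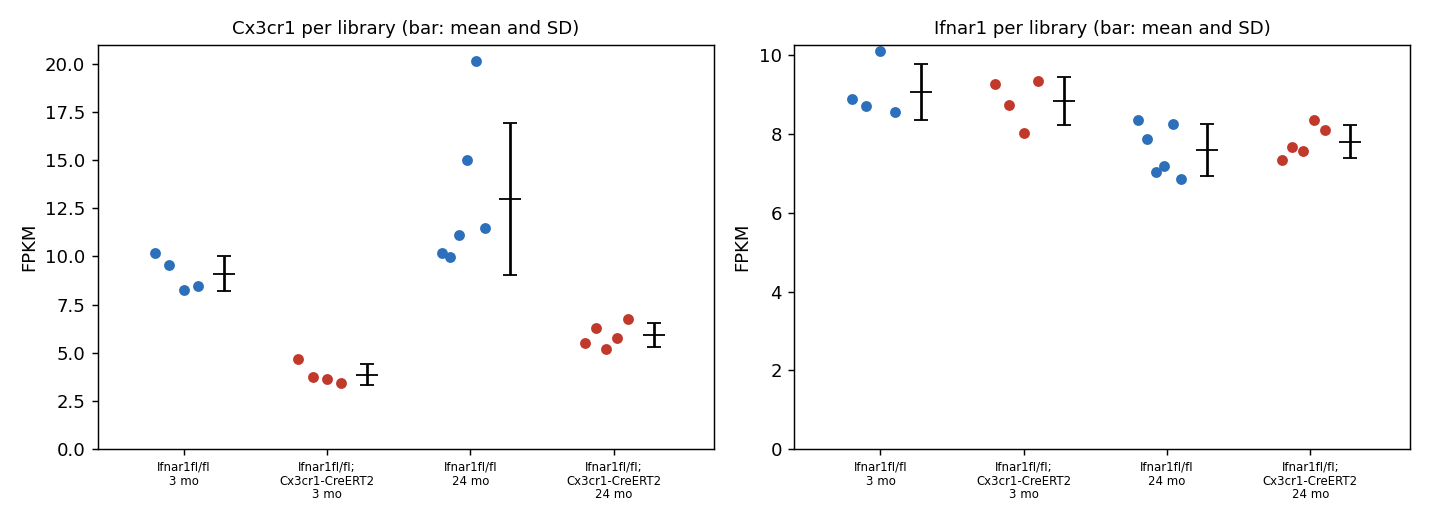
FPKM of Cx3cr1 (left) and Ifnar1 (right) in each library of the 4 Ifnar1 groups, with the mean and SD of each group in black. Cx3cr1 lies at 3.44 to 6.77 FPKM in carriers and at 8.25 to 20.2 FPKM in Ifnar1fl/fl, and the Ifnar1 values overlap.

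Cx3cr1 was the 1 gene that passed at each age by limma, with 454 genes at an unadjusted p below 0.05 at 3 months and 742 at 24 months, where 775.8 are expected by chance. Leaving out a library ended the call in 7 of 8 cases at 3 months (each library except carrier 41, without which Pdzd2 passed as well, while without carrier 48 another gene passed in its place), with adjusted p up to 0.202, and in 4 of 11 at 24 months (3 of them carriers), up to 0.0758. The log2 difference stayed between -1.23 and -1.09, and between -1.10 and -0.90. Of 17 other settings 15 kept the call at each age. The call ended without the libraries with at least 20 FPKM of Ttr at both ages (adjusted p = 0.213 and 0.587), without a filter at 3 months and with only the groups compared at 24 months (adjusted p = 0.441). None of the Ttr-rich libraries was of 3 months, so there the same 8 libraries were compared in a fit with fewer 24-month libraries. The log2 difference ran from -1.22 to -1.06 and from -1.08 to -0.96 over all 17.

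At 24 months the interferon-stimulated genes stood lower in Cre carriers as a list, although no single member passed over all genes. Of 33 members 31 had negative differences, with a median of -0.30 (adjusted p = 4.70e-12), and 2 were lowered adjusted over the list alone, Lgals3bp (-0.95) and Slfn2 (-0.89). The list lost its call with an estimated correlation (adjusted p = 0.530). The library scores averaged 0.00296 ± 0.0611 (SD, n = 5) in carriers and 0.35 ± 0.45 (SD, n = 6) in Ifnar1fl/fl, and did not pass (exact permutation p = 0.0823, adjusted 0.602). The highest score, 1.18, belonged to Ifnar1fl/fl library 230, and without it the list median was -0.14 (adjusted p = 8.96e-07) and the score difference -0.18 (exact permutation p = 0.103). Fold changes at 24 months also followed the GC content of genes, at a Spearman correlation of -0.34 across genes.

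**Figure D4:**
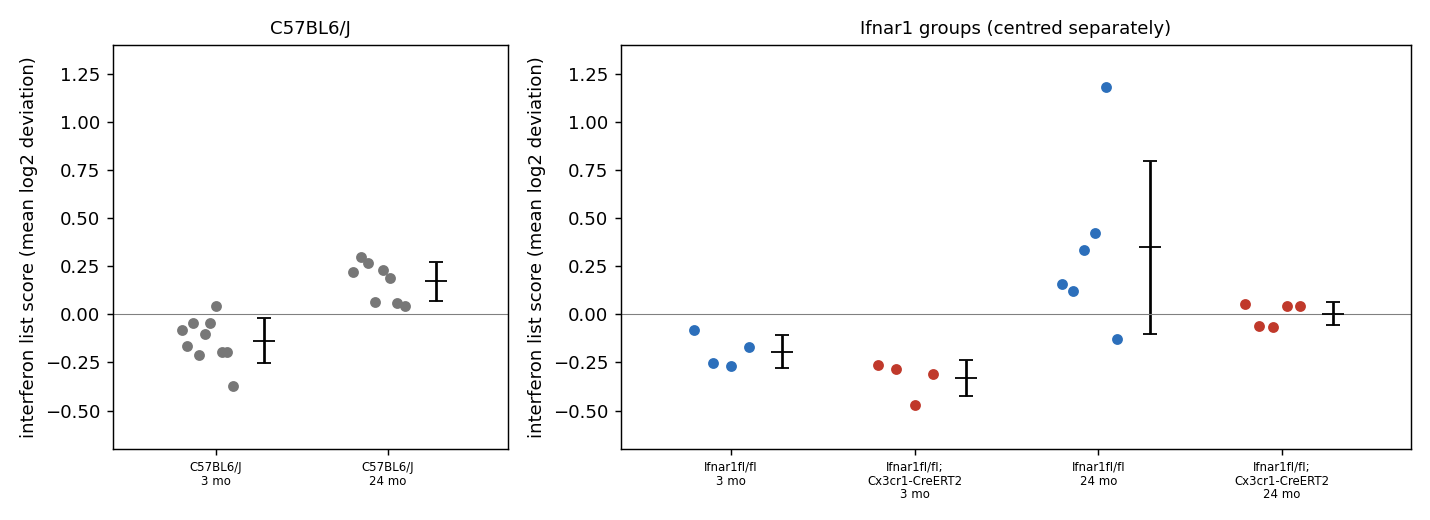
Score of the type I interferon list, as the mean log2 deviation of its genes, in each library of C57BL6/J (left) and of the Ifnar1 groups (right), with the mean and SD in black, each table centred on its own mean. The 24-month Ifnar1fl/fl libraries range from -0.13 to 1.18 and the 24-month carriers from -0.07 to 0.06.

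Immune lists stood lower with it at 24 months. Medians were -0.33 for complement, -0.25 for disease-associated microglia, -0.24 for border-associated macrophages, -0.23 for reactive astrocytes, -0.18 for homeostatic microglia, -0.17 for MHC class I and -0.10 for lysosome. Ribosomal proteins (-0.14), oxidative phosphorylation (-0.07), extracellular matrix (-0.17) and striatum (-0.16, which did not pass under 11 of 17 alternatives or without 7 of the 11 libraries in turn) were lower too, and immediate early genes (0.17), heat shock (0.08), protocadherins (0.08), cholesterol synthesis (0.08) and synaptic genes (0.06) higher. These 17 lists passed with the preset correlation and none held with an estimated one (adjusted p from 0.530 to 0.626). Apart from Cx3cr1, counted among the homeostatic microglia, 0 of their members passed over all genes by limma. The homeostatic microglia list was not tested without Cx3cr1, and its other 17 genes had a median of -0.18. Without library 230 the differences of library scores shrank, for complement from -0.27 to -0.11, disease-associated microglia from -0.26 to -0.08, reactive astrocytes from -0.24 to -0.10, homeostatic microglia from -0.23 to -0.12, MHC class I from -0.29 to -0.19, lysosome from -0.13 to -0.06, ribosomal proteins from -0.13 to -0.07 and immediate early genes from 0.21 to 0.11. Without it the complement, synaptic and cholesterol lists no longer passed, nor did the extracellular matrix list, whose median turned to 0.01. The oxidative phosphorylation, protocadherin, immediate early, synaptic, cholesterol and extracellular matrix lists also lost their call in 1 to 3 of 17 other settings. With each of the 11 libraries left out in turn, the synaptic list lost it in 6 cases, cholesterol in 5 and oxidative phosphorylation in 3. The protocadherin and extracellular matrix lists lost it in 2 cases each.

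At 3 months 8 lists stood lower in Cre carriers and none higher. They were cholesterol synthesis (-0.21, adjusted p = 3.05e-08), protocadherins (-0.10), homeostatic microglia (-0.16), the 6 mitochondrially encoded genes present (-0.59), interferon-stimulated genes (-0.15, adjusted p = 0.0178), lysosome (-0.07), astrocyte (-0.07) and erythroid genes (-0.53). None held with an estimated correlation (adjusted p = 0.537 for cholesterol synthesis, protocadherins and mitochondrial genes, 0.978 for the others). The interferon list lost its call with array weights, with a filter at 2 FPKM, and without Ifnar1fl/fl 40, Ifnar1fl/fl 58 or carrier 49. The erythroid list lost it in 5 of 17 settings and without 6 of the 8 libraries in turn, the astrocyte and lysosome lists each in 1 setting and without 4 libraries, the protocadherins with a filter at 2 FPKM and the mitochondrial genes without Ifnar1fl/fl 40. The cholesterol synthesis and homeostatic microglia lists kept it in all of these. The homeostatic microglia list includes Cx3cr1, whose locus carries the Cre, so its call rests in part on that allele. Its other 17 genes had a median of -0.15, and the list was not tested without Cx3cr1.

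Genes that age changed in C57BL6/J were followed as sets in the genotype comparisons. At 3 months the 65 raised genes had a median of -0.13 (48 of them negative, adjusted p = 0.00842, and 0.501 with an estimated correlation), and the 6 lowered genes did not pass (adjusted p = 0.700). At 24 months the 65 raised genes had a median of -0.04 (adjusted p = 0.0921, and 0.728 with an estimated correlation). The 6 measured lowered genes had a median of 0.07 and a mean of -0.07, opposite in sign, with a test that pointed downward (adjusted p = 0.679). Sets by adjusted p only, of 561 and 483 genes, had medians of -0.04 and 0.04 and passed (adjusted p = 0.00149 for each), and lost that with an estimated correlation (adjusted p = 0.267).

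Finally, the age change itself was compared between both genotypes. By limma 0 genes passed, with 686 at an unadjusted p below 0.05. The lowest p belonged to Gm18609 (0.63), Hirip3 (-0.39), Camk4 (0.47), Gm16054 (0.76) and Ankrd39 (-0.44), all with an adjusted p of 0.965. The difference was 0.11 (SE 0.22) for Cx3cr1 and 0.07 (SE 0.10) for Ifnar1. The age change of 8 lists differed with the preset correlation, among them interferon-stimulated genes (-0.12, adjusted p = 0.0151), and none held with an estimated correlation (adjusted p from 0.577 to 0.942). The interferon list lost its call without the libraries with at least 20 FPKM of Ttr, and without Ifnar1fl/fl 230, 42 or 56, or carrier 41. The disease-associated microglia and reactive astrocyte lists each lost it in 5 of 16 settings and without 8 of the 19 libraries in turn, and the ribosomal list in 1 setting and without 6 libraries. The other 4 lists kept it.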

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

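Chosen only after the result was seen were the tests of library 230, of depth, of GC content, of the striatum list in C57BL6/J, of the 3-month Ifnar1 libraries against C57BL6/J, and of the other microglial genes; the regroupings of the libraries, the microglial covariate and the correlation of striatal markers were set before. The depth bound in particular was widened by the spread after the value was known.

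Among 248 sets of values of 1 gene or list in 1 group, 11 held a library far from the rest, and about 1 in 20 is flagged by chance. In 3-month Ifnar1fl/fl library 58 stood highest for Drd2 at 7.03 FPKM, Lrrc10b at 12.3 FPKM and Six3 at 0.761 FPKM. In 3-month carriers library 48 stood highest for Mt2 at 16.2 FPKM, library 49 lowest for Rn7sk at 3.58 FPKM and library 41 lowest for Mir6769b at 0 FPKM. In 24-month Ifnar1fl/fl libraries Mir7026 reached 0.964 FPKM, Mir3072 0.762 FPKM and Mir374b 2.15 FPKM in 1 library each, and in 24-month carriers Mir344-2 reached 3.56 FPKM in 1 library, with the other libraries of each group at 0. The extracellular matrix score was 0.96 in library 230, with the others from -0.31 to -0.04.

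The age change of 8 lists differed between both genotypes by camera with the preset correlation. The medians of that difference were -0.12 for interferon-stimulated genes, -0.18 for MHC class I, -0.19 for disease-associated microglia, -0.21 for reactive astrocytes, -0.13 for ribosomal proteins, 0.19 for protocadherins, 0.73 for mitochondrially encoded genes and 0.33 for cholesterol synthesis. None held with an estimated correlation, and the interferon, disease-associated microglia, reactive astrocyte and ribosomal lists also lost their call in other settings and without single libraries.

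Regrouping the libraries at random tested the counts of genes. In C57BL6/J the real count of 1051 was reached by 1 of 100 splits, the real one, and the highest other was 2. This argues against chance, to the limit of 1 in 100 that these splits allow. The same holds for Ifnar1fl/fl (5762, 1 of 100, highest other 2069) and for Cre carriers (5725, 1 of 100, highest other 3559). In the Ifnar1 groups the splits cannot separate age from cohort or processing. Chance cannot be excluded for the counts of 1 gene between genotypes at 3 months (4 of 35 splits, highest other 14) and at 24 months (10 of 100, highest other 4). For the difference of age changes the real count is 0, which every split reaches (100 of 100, highest other 8), so the splits decide nothing there. That 1 of the 35 splits at 3 months called 14 genes points to some structure of those libraries, and what it is was not tested.

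The interferon list stood lower in 24-month carriers, by a median of -0.30. With GC trends removed the median was -0.32, which argues against GC content as the whole cause. Whether library 230 accounts for most of the difference cannot be told apart, since the score difference was -0.18 (SE 0.10) without it and -0.34 with it. Depth cannot be told apart, with r = 0.30 (permutation p = 0.421) and rho = 0.11 (permutation p = 0.770) within groups over 11 libraries, and r = 0.33 without the 2 of most distant depth. Fewer microglial transcripts cannot be told apart either, since with the other microglial genes as a covariate the score difference was -0.11 (SE 0.10) against -0.34 (SE 0.20) without it, and the effect of the receptor deletion stays open and untested.

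Striatal markers rose with age in both Ifnar1 genotypes. In C57BL6/J their median was -0.14. That fall lost its call with an estimated correlation and did not pass by exact permutation of library scores. The lack of a rise there argues against age acting alike in C57BL6/J and the Ifnar1 groups, although the difference between them was not tested. With GC and length trends removed the striatal median was still 1.86 or higher in the Ifnar1 groups, a value also taken after the result was seen. The markers varied together between libraries of a group, with a mean pairwise r of 0.80 over 66 pairs in 19 libraries (0.85 in the 8 of 3 months and 0.69 in the 11 of 24 months), in line with different amounts of striatal tissue. For 100% of the markers 3-month C57BL6/J lay closer to the 24-month libraries, so the 3-month Ifnar1 libraries differ from both. Every C57BL6/J library had at least 16.9 FPKM of Drd2 and 136 FPKM of Penk. The 24-month Ifnar1 libraries had at least 13.3 and 105 FPKM, and the 3-month ones at most 7.03 and 82.3 FPKM. If striatal tissue is the cause, the C57BL6/J and 24-month Ifnar1 libraries held more of it than the 3-month Ifnar1 ones. What cortex alone would show cannot be told, since no library known to lack striatum was compared. Striatal tissue in the C57BL6/J and 24-month libraries therefore stays open too, and their values may not be of cortex alone. Age in the Ifnar1 genotypes, dissection and processing stay open, because no label separates age from how and when the libraries were made.

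Cx3cr1 was lower in Cre carriers at both ages. The other 17 homeostatic microglia genes had medians of -0.15 at 3 months and -0.18 at 24 months, none below -0.49, which argues against fewer microglia as the whole cause. Replacement of part of the locus by the Cre allele may be a cause of the lower value, as a hypothesis that gene-level values cannot test.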

How the results depend on the processing

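The removal of libraries by 18S or Ttr, the rescaling without 18S and mitochondrial genes, the Ttr and Drd2 covariates, the GC and length trends and the permutation of scores were chosen after the results were seen. The 1051 genes of C57BL6/J became 518 after rescaling to sums of 1000000, which also changed the genes tested (20017) and the weight of the pseudocount. They became 1031 after rescaling without 18S and mitochondrial genes. They became 594 without the low-18S libraries and 329 without the Ttr-rich ones, both with fewer samples, and 801 to 1086 without single libraries. The 5762 and 5725 genes of the Ifnar1 groups became 375 and 1187 with Drd2 as covariate, which stands close to age there, and 4599 to 5645 and 4628 to 5382 without single libraries. The single gene between genotypes became 0 at 3 months without a filter (28393 genes tested) and 0 at 24 months with only the groups compared. It became 0 at both ages without the Ttr-rich libraries, none of them of 3 months in these genotypes, and 0 to 2 and 0 to 1 without single libraries. The interferon list at 24 months (-0.30) lost its call with an estimated correlation (adjusted p = 0.530) and by permutation of scores (-0.34, and -0.18 without library 230), with medians of -0.40 to -0.14 without single libraries. In C57BL6/J it stayed at 0.23 to 0.28. The age-raised set (-0.04) passed with sets by adjusted p only (-0.0409), a filter at 2 FPKM (-0.0996) and rescaling without 18S and mitochondrial genes (-0.0199), with -0.0860 to -0.00282 without single libraries. The age-lowered set (0.07) passed with adjusted p only (0.0378), turned to -0.0332 without the Ttr-rich libraries, and ranged from -0.0900 to 0.137. With Drd2 as covariate the immediate early list turned to 0.0631 and 0.0346, Adora2a to -0.33 and -0.86 and Penk to -0.31 and -0.55 in Ifnar1fl/fl and carriers. Ifnar1 at 24 months turned to -0.00696 without the Ttr-rich libraries and ranged from -0.0594 to 0.0174 at 3 months without single ones, and the extracellular matrix list ranged from -0.224 to 0.0138. Where no cause is named the cause was not tested. Of the other values of single genes and lists, 1273 and 1368 kept direction and side of the threshold under alternatives other than single libraries, and 101 and 175 lost their call. Relative depth limits values near 0 FPKM.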

Other observations

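In C57BL6/J cortex single genes of further fixed lists passed. The gap junction gene Gja1 of astrocytes fell by 0.16 (SE 0.04), the endothelial gene Itm2a by 0.28 (SE 0.07) and the collagen genes Col1a1 and Col1a2 by 0.41 (SE 0.12) and 0.36 (SE 0.10). Sparc, a matrix protein gene also counted among microglial genes, rose by 0.55 (SE 0.11). The clock genes Bhlhe41 (0.30) and Cry1 (0.18) rose and Nr1d1 fell by 0.21. Among the neuronal markers Pvalb of fast-spiking interneurons rose by 0.23 (SE 0.06).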
